A study of Drosophila melanogaster with 3 samples.

How the data were processed

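Peak lists from ChIP-seq of Ems tagged with green fluorescent protein were analysed for 3 biological replicates of *Drosophila melanogaster* embryos aged 0 to 24 hours. Per the labels, the chromatin was sonicated, with fragments of 200 to 800 bp, and the experiment description names an antibody against the tag. Another field of the labels gives the antibody as ems; the description is followed here, and recovery of untagged Ems by an antibody against Ems is not excluded by the labels. Each replicate had a list of peaks and background regions on dm6 and on dm3. For all 3 together there were a list of the same kind and an optimal list thresholded on the irreproducible discovery rate (IDR), a measure of rank agreement between replicates. Per the notes deposited with the files, each replicate list was called from that replicate's alignments and a control file, the joint list from the alignments of all 3 replicates and a control file, and the optimal list from these lists. The control library was not analysed here. The aligner, the peak caller and the IDR settings are not given in the sources used here. Choices made when reads are mapped, such as how reads with several matches are treated, decide whether repeated sequences such as tRNA gene copies can yield peaks.

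The deposited lists are in the narrowPeak format. The signal column holds the peak signal as deposited by the authors, on a scale that the sources used here do not give. It was larger in the joint list than in single replicates, so it was used only to rank peaks within a list. The −log10 q column, also deposited by the authors, was used to count peaks with q-values under 0.01. The summit offset column, deposited as a distance in bp from the start of each interval, gave each summit. Coordinates are printed 1-based and on dm6, and none was converted between builds; the dm3 lists were used for counts and overlaps only. The lists hold no read counts, so the depth of each sample is unknown, and intervals on shares of peaks cover counting error only.

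Summits were annotated with the Ensembl gene annotation, release 115, of the Release 6 assembly, which is the assembly of dm6. Each base of the arms X, 2L, 2R, 3L, 3R and 4 had 1 of 7 classes, assigned in the order promoter (within 500 bp of the TSS of a protein-coding gene), 5' UTR, 3' UTR, coding exon, intron, other exon and intergenic. Class shares were tested against 10000 random placements of as many summits on the same arms, outside gaps. Overlap between replicates was tested with 1000 rotations of each replicate's peaks along the arms. Arms were compared with an exact binomial test. For replicates, the 3866 highest-signal peaks of each list were used, as many as the optimal list holds, and means and SDs are over n = 3.

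6-mers were counted on either strand within 100 bp of summits and in windows of the same length centred 500 bp away. Percentages for flanks are means of both sides. The exact McNemar test set each summit window against 1 flank drawn per peak. Among 16 fixed motifs, 7 were palindromes of 3 A and 3 T other than TAATTA, as controls for base composition. Of these, ATTAAT itself contains TAAT, so it is not a clean control. The trend of TAATTA with signal was tested with 100000 permutations. Gene lists were tested against 10000 random lists of genes matched on gene length (5 groups of equal size) and number of TSSs (1, 2, or 3 and more). The random lists were drawn without replacement from genes outside the list. For gene lists, the p from these draws is called a permutation p. The smallest two-sided p these draws can give is 0.0002. Log2 ratios of gene lists are of bound to expected counts, with the same small constant added to both. For a list with no bound gene, the log2 ratio therefore depends only on the number expected. Adjustment was by Benjamini-Hochberg within each family, at a threshold of 0.05. For 3 list members given by older symbols the annotation's current ones are used, *hry*, *dysf* and *Delta*, and all members were found.

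Lists, motifs, tests and alternatives were fixed before the data were examined, as was the rule for the genes named. It takes *ems*; the protein-coding genes nearest to the 25 highest-signal peaks present in all 3 replicates; up to 4 members of each list with the highest bound peak, and the unbound members of lists of 12 or fewer genes; and the 5 most and 5 least enriched 6-mers called. Further bound list members and the genes of coding-exon peaks were named after their values were seen. The positions of summits relative to the TSS, 8-mers, 7 further gene families, genes of other RNA classes, divergent promoters and 20 repeated shuffles were added after the data were seen. Alternatives covered the promoter, motif and TSS windows, gene bodies with 2 kb to each side, the flank distance, shuffled windows and a stricter signal threshold. They also covered the overlap rule, the number of peaks per replicate, the lowest-signal peaks as background, the dm3 lists and leaving out each replicate.

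The steps were tested on simulated data. For promoter placement, 20 simulations of 3866 random summits gave 0 calls, and 20 with an expected promoter share of 46.9% gave a mean of 47.0% and 20 calls. In the 6-mer test, unchanged random windows gave 0 calls over 2080 6-mers, and all 5 planted 6-mers were recovered with 14 others, of which 12 shared 5 bases in a row with a planted one. These windows lay at random positions, without the GC difference between summits and flanks in the data. Calls caused by such a difference were therefore not tested. In the gene-list test, 8 of 200 unchanged lists of 60 genes and 200 of 200 with 40.0 percentage points added passed an unadjusted p of 0.05. Binding was drawn independently for each gene there, while in the data 1 peak can call several genes bound. The error rate for lists of neighbouring genes was therefore not tested. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.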

Results

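Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole *Drosophila melanogaster* embryos of both sexes, collected 0 to 24 hours after laying. The embryos carried a transgene for Empty spiracles (Ems) fused to green fluorescent protein. Per the experiment description, the chromatin was recovered with an antibody against that tag, although another field of the labels gives the antibody as ems. Ems is a homeodomain transcription factor needed for the head, parts of the brain, the tracheal system and the posterior spiracles. The series held 1 group of 3 biological replicates, so no comparison between groups was possible, and each pattern was set against random or matched genomic positions. The SD over the 3 replicates measures the spread between these samples, and the p-values rest on peaks or genes, which are not replicates. The optimal list, the set of reproducible peaks that the authors derived from all 3 replicates, held 3866 peaks on dm6 and 3963 on dm3. The peaks had a median width of 404 bp. Their signals are the authors' own values and serve here only to rank peaks within a list. On dm6, each replicate's own list, which also holds background regions, had 30000 entries. Of these, 3527 had a q-value under 0.01 in replicate 1, 4276 in replicate 2 and 4599 in replicate 3. Read depth is unknown, because the peak lists give no read counts.

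The *ems* locus was examined first, as the locus of the tagged gene. *ems* (FBgn0000576) lies on chromosome arm 3R from 13901853 to 13904620 of dm6, on the forward strand. Within the gene and 10 kb to each side, the optimal list held 1 peak, from 13903687 to 13904090, whose summit at 13903889 fell in a coding exon of *ems*. It ranked 3457 of 3866 by signal. In the whole lists of replicates 1, 2 and 3 the matching peak ranked 3777, 4190 and 3829, close to the cutoff of 3866 in each. Among the 3866 highest peaks of each replicate, 1 lay in this region in replicate 1, 0 in replicate 2 and 2 in replicate 3. Further from the gene, on the side of its 3' end, 2 intergenic peaks were present in all 3 replicates. The first, from 13914849 to 13914966, had its summit 10299 bp from the gene and ranked 606; the other, from 13915666 to 13916069, lay 11248 bp away and ranked 1755. No optimal summit lay within 1 kb of the *ems* transcription start site (TSS). The count at the locus went from 1 to 0 when only peaks matched in replicates 2 and 3, or only those matched in replicates 1 and 2, were kept.

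**Figure D1:**
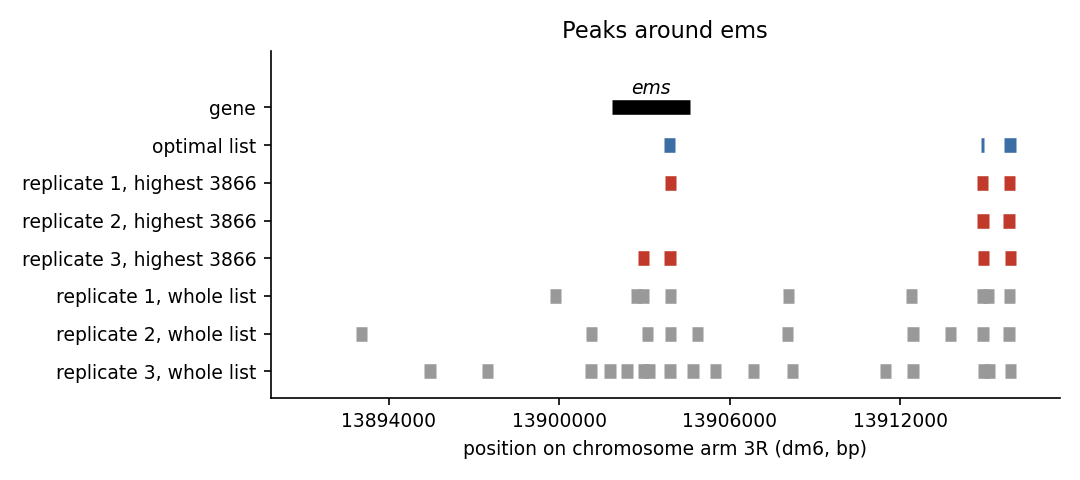
Peaks around *ems* on chromosome arm 3R, with the dm6 position in bp on the horizontal axis and a line for each peak list: the optimal list, the 3866 highest-signal peaks of each replicate and the whole list of each replicate. The coding-exon peak is missing from the 3866 highest peaks of replicate 2, where it ranked 4190 and is in the whole list. The 2 peaks over 10 kb from the 3' end appear in every line.

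The replicates shared most of the strongest peaks. Of the 3866 optimal peaks, 2499 (64.6%) overlapped by at least 1 bp a peak among the 3866 highest of every replicate. The share was 79.3% for replicate 1, 85.7% for replicate 2 and 88.0% for replicate 3, and 21 optimal peaks (0.543%) matched none of the 3. Rotating each replicate's peaks along the chromosome arms left a mean of 0.000698% matched in all 3 (two-sided randomization p = 0.002, the smallest that 1000 rotations can give; n = 3866 peaks). Among the 1933 optimal peaks of higher signal 96.5% were matched in all 3 replicates, against 32.8% of the 1933 of lower signal. Spearman's rho between the signals of 2 replicates across optimal peaks was 0.689 for replicates 1 and 2, 0.732 for 1 and 3 and 0.760 for 2 and 3. These correlations run across peaks, which are not independent replicates. The optimal list was itself made from these replicates and was identical to the 3866 highest peaks of the list called on all replicates together, so the overlap is not independent of it. With the whole list of each replicate the matched share was 99.3%.

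Promoters held more peaks than any other class, and coding sequence held almost none. Of the 3866 summits, 2113 (54.7%) lay within 500 bp of the TSS of a protein-coding gene, 4.76 times the 11.5% of random placements; the share was 46.09% within 250 bp and 63.6% within 1000 bp. Introns held 1161 summits (30.03%, against 39.4% at random) and intergenic sequence 484 (12.5%, against 28.7%). Coding exons held 15 summits (0.388%, against 13.3%) and 3' untranslated regions (UTRs) 26 (0.673%, against 5.17%). Each of these 5 shares differed from 10000 random placements on the same arms (n = 3866 summits, two-sided randomization p = 0.0002, the smallest these can give, and adjusted p = 0.00028 by Benjamini-Hochberg over 7 classes). The shares of 5' UTRs (0.543%, against 0.796%; adjusted p = 0.0961) and of other exons (1.19%, against 1.16%; adjusted p = 0.925) did not pass the test (n = 3866 summits). In the replicates' own lists of 3866 peaks, the promoter share was 54.8% ± 0.797 (SD, n = 3), the intron share 29.6% ± 1.40 and the intergenic share 11.7% ± 1.07. The coding-exon share was less even: 3.23% in replicate 1 (125 summits), 0.388% in replicate 2 and 0.595% in replicate 3. Among optimal peaks matched in both other replicates, the coding-exon share was 0.202% without replicate 1 and 0.259% without replicate 3. In 5 groups of optimal peaks of equal size, ordered from lowest to highest signal, the promoter share was 50.3%, 52.7%, 51.2%, 58.0% and 61.2%.

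**Figure D2:**
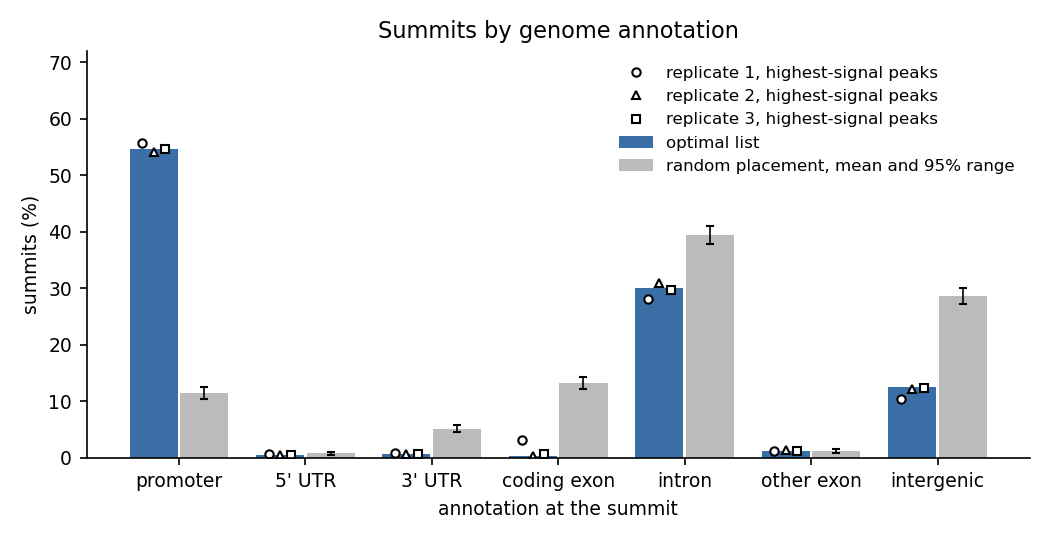
Share of summits (vertical axis, %) in each annotation class for the optimal list (blue bars), for random placements (grey bars with the 95% range) and for the 3866 highest-signal peaks of each replicate (points). Promoters hold 54.7% of optimal summits against 11.5% at random, and replicate 1 lies above the other replicates in coding exons at 3.23%.

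Promoter summits gathered just upstream of the TSS. The median position was 79 bp upstream, with quartiles at -159 and -17 bp, and 1697 of the 2113 (80.3%) lay upstream of the nearest TSS.

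**Figure D3:**
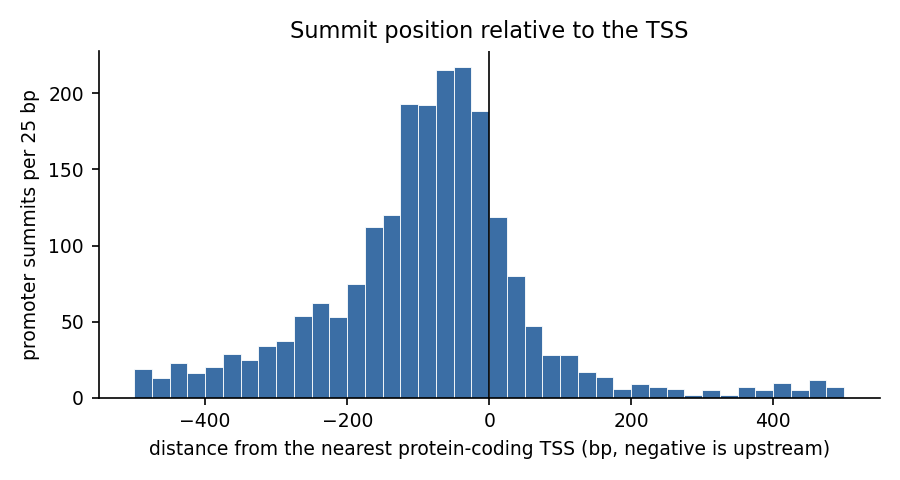
Number of promoter summits per 25 bp (vertical axis) by their distance from the nearest protein-coding TSS in bp (horizontal axis, negative values upstream). The counts are highest in the 125 bp before the TSS and fall steeply after it.

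The strongest peaks lay mostly at promoters. Of the 25 highest-signal peaks matched in all 3 replicates, 16 were in promoters, 5 in introns, 3 in intergenic sequence and 1 in another exon, and none ranked below 30 in any replicate's list. The highest, on 3L from 19590429 to 19590818, had its summit 97 bp from the TSS of *CG14100*. The next, in an intron on 2L (480887 to 481306), was nearest to the TSS of *cbt*, a zinc finger transcription factor gene, 1370 bp away. Its summit lay outside *cbt* but inside *ush* (476220 to 540560), a gene of the dorsal-ventral and of the blood and fat body lists. It was not within 1 kb of a *ush* TSS, so it does not count as the *ush* peak in those lists. Promoter peaks of this set belonged to *Ugalt* (a UDP-galactose transporter; X, 2703696 to 2704080), *px*, *PNPase* (mitochondrial polynucleotide phosphorylase), *Chro* (the chromodomain protein Chromator; 3L, 22878714 to 22879090) and *ph-p* (a Polycomb group gene; X, 2137177 to 2137535). Others lay at the promoters of *mRpL41* (a mitochondrial ribosomal protein), *CG1888*, *CenG1A*, *Art3* (an arginine methyltransferase), *larp* (an RNA-binding protein), *CG18549*, *Sox14*, *CG31145*, *CG9147* and *GstE13* (a glutathione S-transferase). The peaks nearest to *CG11050*, *Lk6* (a protein kinase), *CG32772* and *CG9663* were intronic, and those nearest to *tara*, *eEF1gamma* (a translation elongation factor) and *CG13323* intergenic. The peak nearest to *CG4004* lay in a non-coding exon 5115 bp from its TSS.

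Peak density was even over the large chromosome arms and low on chromosome 4, the small and largely heterochromatic chromosome. Chromosome 4 held 14 summits, or 10.5 per Mb (exact Poisson 95% interval 5.75 to 17.6, counting error only), 0.364 times its share of sequence (two-sided exact binomial test, adjusted p = 6.14e-05 over 6 arms). In the replicates' lists its density was 12.5 ± 1.89 per Mb (SD, n = 3). The densities of 2L (30.3 per Mb), 2R (27.9), 3L (27.7), 3R (29.7) and X (30.2) did not pass the test, with adjusted p between 0.331 and 0.337.

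Homeodomain proteins such as Ems bind cores containing TAAT, so the palindrome TAATTA was counted near summits. It lay within 100 bp of 584 summits (15.1%), against 10.99% of windows centred 500 bp to each side, a ratio of 1.37 (two-sided exact McNemar test, adjusted p = 7.91e-07 over 16 motifs). The ratio was 1.28 ± 0.173 in the replicates' lists (SD, n = 3), with 1.09 in replicate 1, 1.43 in replicate 2 and 1.32 in replicate 3. Each of the 7 other palindromes made of the same bases had a ratio at least as large, from 1.376 for TATATA, close to the 1.374 of TAATTA, to 2.02 for TTTAAA. TATATA was below TAATTA in replicate 1 (1.064), in replicate 3 (1.31) and at promoters (1.39), and ATTAAT was below it outside promoters (1.09). Summit windows held 37.5% GC and flanking windows 43.6%; in replicate 1 the summit value was 40.1%. When each summit window was compared with its own bases shuffled so as to keep dinucleotide counts, the log2 ratio of TAATTA changed from 0.46 to -0.10 (exact McNemar test, adjusted p = 0.195). At promoter summits the ratio to flanks was 1.66 (exact McNemar test, adjusted p = 4.23e-09) and at other summits 1.13 (adjusted p = 0.0307, over both places and 16 motifs).

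In the same exact McNemar test, TAATGA, a variant homeodomain core, had a ratio of 1.21 (adjusted p = 0.0188), AGATAA, a GATA factor core, 1.27 (adjusted p = 0.000431) and TTTATG, a Caudal and Abdominal-B type core, 1.12 (adjusted p = 0.0414). TAATCC, the core of Bicoid and Orthodenticle, was less frequent at summits than in flanks, with a ratio of 0.829 (exact McNemar test, adjusted p = 0.0488). CAGGTA, bound by Zelda, had a ratio of 0.849 (exact McNemar test, adjusted p = 0.178), TGACCT 0.770 (adjusted p = 0.0636), CACGTG 0.865 (adjusted p = 0.940) and GAGAGA, bound by GAGA factor, 1.01 (adjusted p = 0.940). With flanks centred 1000 bp away TAATGA (exact McNemar test, adjusted p = 0.145), AGATAA (0.213), TTTATG (0.121) and TAATCC (0.0758) did not pass the test, TAATCC also did not when any replicate was left out, and against shuffled windows the log2 ratios of TAATGA, TTTATG and AGATAA were below 0. Within 50 bp of summits TAATGA (exact McNemar test, adjusted p = 0.298) and TAATCC (0.741) did not pass the test, while AGATAA (0.0139) and TTTATG (0.0337) did. Among the 1933 optimal peaks of higher signal TAATCC did not pass it (exact McNemar test, adjusted p = 0.738), while TAATGA, AGATAA and TTTATG did. GAGAGA depended on the comparison, with log2 ratios of -0.43 within 50 bp of summits, 0.28 within 200 bp, 0.38 against flanks 1000 bp away and 1.31 against shuffled windows, while TGACCT and CAGGTA passed the test as less frequent at summits under several alternatives, among them shuffled windows.

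The presence of TAATTA did not follow peak strength. Spearman's rho between peak signal and TAATTA across the 3866 optimal peaks, which are not independent replicates, was 0.00601 (two-sided permutation p = 0.709). The share with TAATTA was 14.5% in the lowest of 5 signal groups (95% exact binomial interval 12.1 to 17.1, counting error only) and 15.4% (12.9 to 18.1) in the highest. The ratio to flanks was 1.204 in the lowest group, where flanks held 12.02%, and 1.51 in the highest, where they held 10.22%; a trend in this ratio was not tested. In the separate lists rho was 0.0516 for replicate 1 (permutation p = 0.0013), 0.0111 for replicate 2 (permutation p = 0.492) and -0.00561 for replicate 3 (permutation p = 0.726).

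**Figure D4:**
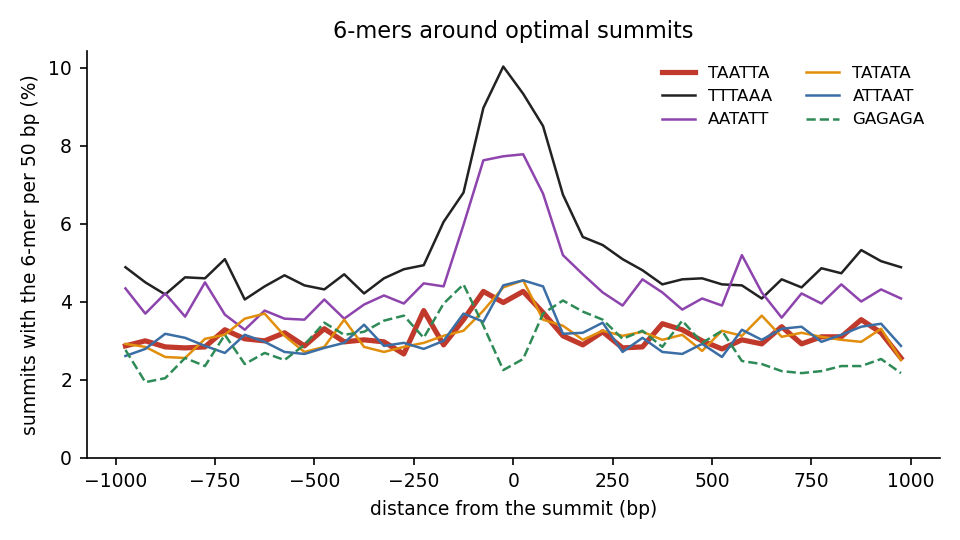
Share of optimal summits with a 6-mer in each 50 bp bin (vertical axis, %) by distance from the summit in bp (horizontal axis) for TAATTA, for 4 palindromes of the same bases and for GAGAGA. TAATTA rises little at the summit (4.27% of summits in the bin centred 25 bp after it), while TTTAAA reaches 10.04% in the bin centred at -25 bp.

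A search over all 2080 6-mers, with reverse complements joined, found 521 more frequent at summits than in flanks and 825 less frequent, in the same direction in every replicate (exact McNemar test with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 1431. The largest ratios were those of CGATAG (3.30, in 13.3% of summit windows against 4.05% of flanks), ACACTG (2.85, 20.7% against 7.27%), TATCGA (2.49), ACAGTG (2.26) and ATCGAT (2.20). In the replicates' lists the ratio of CGATAG was 2.68 ± 0.268 and that of ACACTG 2.63 ± 0.141 (SD, n = 3). TATCGA and ATCGAT are parts of TATCGATA, the element bound by the promoter factor DREF, and ACACTG shares bases with the core promoter element known as motif 1. The lowest ratios were those of CCAGGA (0.224, 1.89% against 8.42%), GGAGGA (0.283), CTCCTC (0.288), CGAGGA (0.293) and CCTCCG (0.301). TAATTA ranked 284 by ratio. The calls largely followed base composition. Of the 521, 3.84% had at most 2 A or T bases, against 34.6% of all 6-mers. Of the 825, 3.39% had at least 4 A or T bases, against 34.6% of all. With shuffled summit windows as the background, 158 6-mers were more frequent at summits, of which 129 were among the 521. Against that background 303 were less frequent, of which 198 were among the 825.

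Genes were called bound when an optimal summit lay within 1 kb of a TSS, which held for 3098 of 13945 protein-coding genes (22.2%; 22.2% ± 0.155 in the replicates, SD, n = 3). Of 2460 summits with such a TSS, 1053 (42.8%) had 2 or more genes in reach, so 1 peak can call several genes bound. Genes of the cytoplasmic ribosome were bound far more often than matched genes, and chemoreceptor and cuticle genes far less often. Of 88 ribosomal protein genes, 60 were bound (68.2%), against 19.5 expected from genes matched on length and number of TSSs (two-sided test against random matched lists, adjusted permutation p = 0.0014 over 21 lists). In the replicates' lists the share was 66.7% ± 3.99 (SD, n = 3). The highest peaks were those at *RpS27* (rank 78), *RpL32* (rank 115), *RpL34b* (rank 172) and *RpL14* (rank 197), each in the promoter and in all 3 replicates. For 50 of the 60 the nearest TSS was the gene's own, and 45 had a peak present in all 3 replicates.

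Chemoreceptor genes, which act in sense organs, and genes for structural proteins of the cuticle were rarely bound. Among 179 olfactory, gustatory and ionotropic receptor genes, 1 was bound, *Or88a*, against 34.7 expected, and among 70 cuticle protein genes 1, *Cpr73D*, against 10.9 (adjusted permutation p = 0.0014 for each list). In both cases the summit was nearer to the TSS of another gene. The replicates' lists gave 1.12% ± 0 of chemoreceptor genes and 2.38% ± 1.65 of cuticle genes (SD, n = 3). With a 5 kb window the cuticle list did not pass the test (adjusted permutation p = 0.1). None of the 10 eggshell genes (*Cp15*, *Cp16*, *Cp18*, *Cp19*, *Cp36*, *Cp38*, *Vm26Aa*, *Vm26Ab*, *Vm32E* and *Vm34Ca*) was bound, against 1.03 expected (adjusted permutation p = 0.765).

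None of the lists of embryonic patterning genes passed the test at the 1 kb window. Of the 11 head gap and head patterning genes 1 was bound, the bZIP factor gene *cnc* (rank 1463), against 2.83 expected (adjusted permutation p = 0.599). The unbound members were *oc*, *ems*, *btd*, *slp1*, *slp2*, *tll*, *gt*, *hb*, *croc* and *knrl*. No Hox gene was bound (0 of 8: *lab*, *pb*, *Dfd*, *Scr*, *Antp*, *Ubx*, *abd-A* and *Abd-B*; 2.79 expected, adjusted permutation p = 0.206). Nor was any gap and trunk gene (0 of 10: *hb*, *Kr*, *kni*, *knrl*, *gt*, *tll*, *hkb*, *cad*, *nub* and *pdm2*; 2.98 expected, adjusted permutation p = 0.206) or pair-rule gene (0 of 9: *eve*, *hry*, *run*, *ftz*, *odd*, *prd*, *opa*, *slp1* and *slp2*; 2.05 expected, adjusted permutation p = 0.389). The gap and trunk list was past the threshold with a 5 kb window (log2 ratio -3.39, adjusted permutation p = 0.0252). The 1 kb window leaves out peaks further inside a gene. With summits in gene bodies and 2 kb to each side counted, the log2 ratio of Hox genes went from -2.72 to -0.44. That of gap and trunk genes went from -2.80 to -0.98, that of dorsal-ventral genes from -0.57 to 0.52 and that of pair-rule genes from -2.35 to -2.89. None of these lists passed the threshold with gene bodies. No pair-rule gene was bound in either setting, so the change in its log2 ratio reflects only a larger number expected. Segment polarity genes were bound in 3 of 14 cases, the Wnt antagonist gene *nkd* (rank 1141) and the Hedgehog pathway genes *smo* and *ptc* (3.84 expected, adjusted permutation p = 0.915). Dorsal-ventral genes were bound in 4 of 20 (*brk*, a repressor of Dpp targets, at rank 836, *ush*, *Ance* and *rho*; 6.16 expected, adjusted permutation p = 0.599).

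Lists for tissues in which *ems* is known to act did not pass the threshold either. With gene bodies and 2 kb to each side counted, the log2 ratio of posterior spiracle genes went from -0.65 to 0.33. That of trachea genes went from 0.055 to 0.24, that of olfactory projection neuron genes from -0.31 to 0.40 and that of brain homeobox genes from -1.19 to -0.59. None of these passed the threshold. Posterior spiracle genes were bound in 3 of 17 (*crb*, an apical polarity gene, at rank 1813, *Cad96Ca* and *trh*; 5.002 expected, adjusted permutation p = 0.599). Trachea genes were bound in 5 of 16, with *aop* (rank 1684) and the FGF gene *bnl* (rank 1715) highest, then *trh*, *pnt* and *rho* (4.80 expected, adjusted permutation p = 1.0). Brain homeobox and retinal determination genes were bound in 2 of 16, *ey* and *so* (5.22 expected, adjusted permutation p = 0.293). Neither peak was present in all 3 replicates. With only optimal peaks matched in replicates 2 and 3 kept, the log2 ratio of this list went from -1.19 to -3.23 (adjusted permutation p = 0.0588). With only those matched in replicates 1 and 2 kept, it went to -3.14 (adjusted permutation p = 0.102). Olfactory projection neuron genes were bound in 3 of 12, the zinc finger gene *lola* (rank 747), *Ten-a* and *Sema1a* (3.83 expected, adjusted permutation p = 0.915); *acj6*, *vvl*, *Lim1*, *ct*, *ems*, *chinmo*, *Dscam1*, *Ten-m* and *caps* were not.

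The remaining lists covered neural precursors and other cell types, and none passed the threshold. Neuroblast and proneural genes were bound in 3 of 20, *brat* (rank 196), *numb* (rank 478) and *pros*, which act in asymmetric division (5.04 expected, adjusted permutation p = 0.599). No temporal neuroblast gene was bound (0 of 9: *hb*, *Kr*, *nub*, *pdm2*, *cas*, *grh*, *svp*, *dan* and *danr*; 3.29 expected, unadjusted permutation p = 0.0304, adjusted p = 0.16). Glial genes were bound in 5 of 11, led by the blood-brain barrier receptor gene *moody* (rank 93) and the glutamine synthetase gene *Gs2* (rank 365), then *nrv2*, *pnt* and *loco* (3.71 expected, adjusted permutation p = 0.716); *gcm*, *gcm2*, *repo*, *ttk*, *wrapper* and *alrm* were unbound. Neuronal genes were bound in 2 of 13, *elav* (rank 116) and *Syx1A* (5.12 expected, adjusted permutation p = 0.293). Muscle genes were bound in 4 of 25, the myoblast fusion genes *mbc* (rank 641) and *rols*, *sls* and *tin* (8.37 expected, adjusted permutation p = 0.244). In the gut and endoderm list *fkh* (rank 1298) was bound and *srp*, *GATAe*, *bin*, *byn*, *hkb*, *cad* and *lab* were not (2.41 expected, adjusted permutation p = 0.642). In the blood and fat body list *ush* (rank 1691) was bound and *srp*, *lz*, *gcm*, *Pxn*, *NimC1*, *Hml*, *Fbp1*, *Fbp2*, *Lsp2* and *Lsp1alpha* were not (3.34 expected, adjusted permutation p = 0.389). Keeping only optimal peaks matched in both other replicates also moved the log2 ratio of segment polarity genes from -0.31 to -1.23 (without replicate 1) and -1.14 (without replicate 3). That of posterior spiracle genes went from -0.65 to -1.51 (without replicate 2) and -1.49 (without replicate 3), and that of trachea genes from 0.055 to -0.72 and -0.69 (without the same replicates). None was past the threshold. This filter leaves fewer peaks, so these shifts cannot be laid to the replicate named. With gene bodies and 2 kb to each side counted, the log2 ratio of temporal neuroblast genes went from -2.92 to -1.04. The nearest TSS was the gene's own for 2 of 3 bound segment polarity genes, 3 of 4 bound muscle genes and 1 of 2 bound brain homeobox genes. It was the gene's own for every bound gene of the other lists of 8 to 25 genes. These lists are small, so a p that misses the threshold does not show that they equal matched genes, and several genes stand in more than 1 list.

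**Figure D5:**
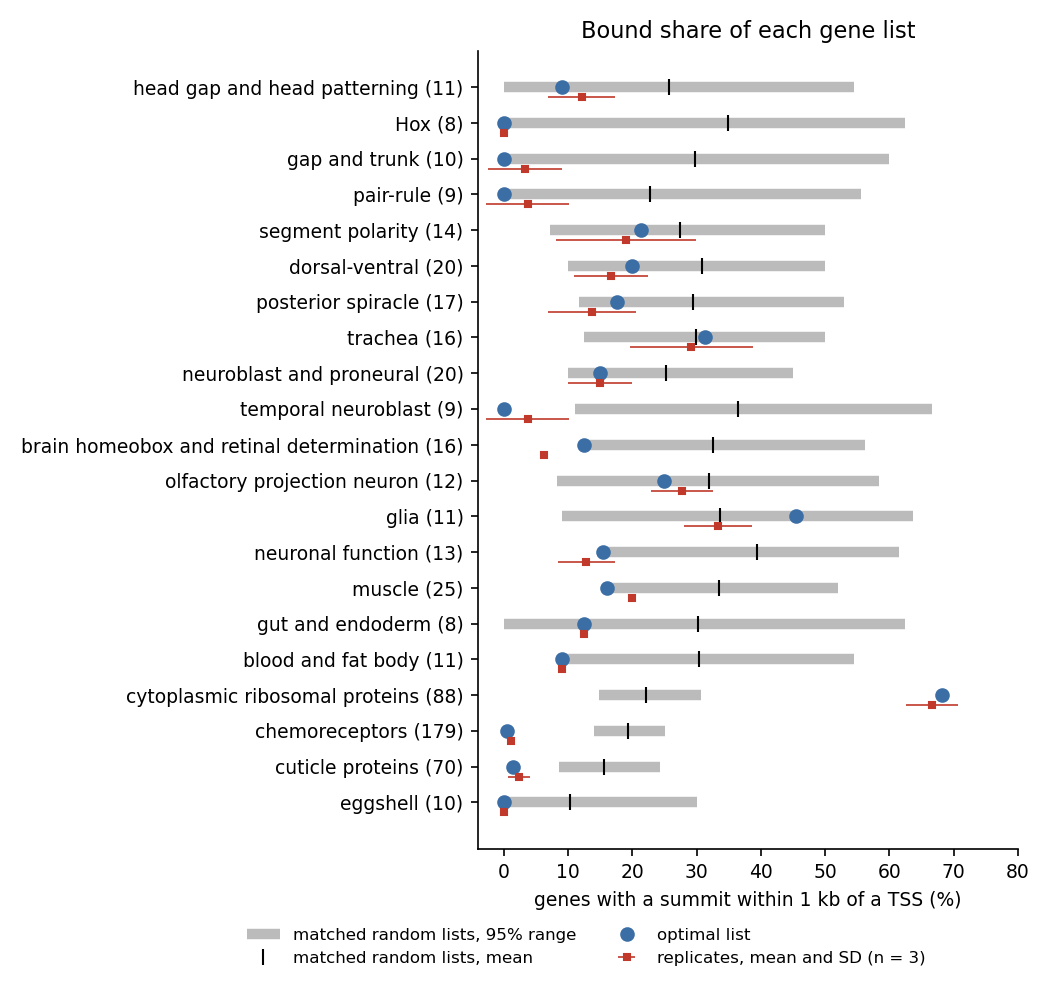
Share of genes with a summit within 1 kb of a TSS (horizontal axis, %) in each of 21 fixed lists, with list sizes in brackets: blue points for the optimal list, red squares for the mean and SD of the 3 replicates, black ticks and grey bars for the mean and 95% range of matched random lists. Ribosomal protein genes lie above their matched range at 68.2%, and chemoreceptor and cuticle genes lie below theirs.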

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

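Groups of 3 samples are too small for a search for outlying samples, and 1 group allows no comparison of effects between groups. Signals were present in parts of the lists that the comparisons above do not use. The class shares and overlaps of the peaks below were computed after their number had been seen. The joint list of all replicates held 830 peaks with a q-value under 0.01 that are not in the optimal list. Of these, 50.4% lay in promoters and 2.65% in coding exons, and 38 (4.58%) overlapped a peak among the 3866 highest peaks of every replicate. On dm3, the joint list held 31 peaks on sequences outside the 6 arms used here, while the optimal dm3 list held 0.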

How the results depend on the processing

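Repeated shuffling (20 shuffles) was the alternative chosen after the data were seen. Of 407 alternative values for 53 results, 366 kept their side of the threshold or stayed within the tolerance set for counts and values. Among them were all 32 for class shares and 166 of 168 for gene lists. A change of direction counted against a result only where either value passed the threshold. Several gene lists changed direction with neither value past it. For dorsal-ventral genes, the log2 ratio went from -0.57 to 0.52 with gene bodies and 2 kb to each side. The share of optimal peaks matched in all 3 replicates ranged from 55.0% (reciprocal overlap of at least 50%) to 99.3% (whole list of each replicate), with 69.8% to 77.0% when a replicate was left out and the other 2 had to match. With dinucleotide-shuffled windows as the background, the log2 ratio of TAATTA reversed to -0.10, with a mean of -0.067 over 20 shuffles, and 158 6-mers were more frequent at summits in place of 521. Under the same background the log2 ratios of TAATGA (-0.44), TTTATG (-0.14), AGATAA (-0.13), AAATTT (-0.17), ATTAAT (-0.17) and TTATAA (-0.12) also reversed; this background holds the base composition of the summits themselves, which the flanks do not. GAGAGA reversed to -0.43 within 50 bp. Against the lowest-signal peaks, the density of arm X passed the threshold (log2 ratio 0.13, adjusted p = 0.0312, exact binomial test). With a 5 kb TSS window the gap and trunk list passed it (log2 ratio -3.39) and the cuticle list no longer did (log2 ratio -0.65). For GAGAGA, arm X and the 2 lists the cause was not tested. No paired analysis was possible because the series holds 1 group. The *ems* locus held 3 optimal peaks within 50 kb, and 0 to 1 within 10 kb when a replicate was left out. On dm3 the peaks per arm were only counted (731 on 2L, 14 on chromosome 4), since arm lengths were not taken across builds. Read depth is unknown, so how far it limits the weaker peaks could not be judged.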

Other observations

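The added gene families, the 8-mers, the divergent promoters, the coding-exon lists, the palindrome count, the 20 shuffles, the tRNA and snRNA shares and the *ems* percentiles are tests chosen only after the result was seen. Genes of the mitochondrial ribosome were bound more often than matched genes, with 29 of 73 (39.7%, against 12.9% expected, two-sided test against random matched lists, adjusted permutation p = 0.0014 over 7 families). Translation initiation factor genes were bound in 17 of 44 (38.6%, against 22.9%; adjusted permutation p = 0.0462). Proteasome subunit genes (8 of 48, against 9.06 expected; adjusted permutation p = 0.861) and genes of complex I and cytochrome oxidase (14 of 56, against 11.7 expected; adjusted p = 0.628) did not pass the test. Odorant-binding protein genes were bound in 1 of 51 (*Obp99b*; 7.40 expected, adjusted permutation p = 0.0189), accessory gland protein genes in 1 of 47 (*Sfp26Ad*; 5.25 expected, adjusted p = 0.0861) and Jonah and trypsin protease genes in 0 of 26 (2.67 expected, adjusted p = 0.163). The replicates' lists gave 36.5% ± 2.85 for the mitochondrial ribosome and 35.6% ± 3.47 for initiation factors (SD, n = 3).

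Among 8-mers, TATCGATA, the DREF element, had the largest ratio of summits to flanks. It lay within 100 bp of 208 summits (5.38%, against 0.569% of flanks, adjusted p = 2.14e-33 by the exact McNemar test over 26290 8-mers). Almost all of these were promoter summits, 201 of 2113 (9.51%, exact binomial interval 8.29 to 10.8), while 7 of 1753 other summits had it (0.399%, the same as their flanks). From the lowest to the highest of 5 signal groups its share was 6.07%, 5.43%, 5.95%, 5.82% and 3.62%, lower only in the highest group (Spearman's rho -0.0326 across peaks, unadjusted permutation p = 0.0419). Other leading 8-mers were CACTGAGA (3.96% against 0.504%) and CAGCCCTG (2.51% against 0.336%). Promoter summits also lay within 500 bp of TSSs on both strands more often than chance: 780 of 2113 (36.9%), against 10.97% for random promoter bases and 26.7% for random TSSs at the same distances (95% range 24.8 to 28.6; n = 2113 summits, two-sided randomization p = 0.0002, the smallest these can give). The background of equal distances was added after the first comparison had been seen. In the replicates' lists this share was 35.5% ± 2.94 (SD, n = 3).

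The 15 optimal summits in coding exons lay in *Rab30*, *Pde1c*, *par-1*, *otp*, *CG10321*, *klar*, *RpL8*, *CG5895*, *corto*, *Hph*, *ems*, *Orp8*, *CG31457*, *Acf* and *bif*. The strongest was in *otp* (rank 114), a homeobox gene, on 2R from 20884451 to 20884693. The larger coding-exon share of replicate 1 came from its lower ranks: among its 1933 highest peaks the share was 0.569%, against 3.23% in the 3866 highest. For replicates 2 and 3 the shares among the 1933 highest were 0.155% and 0.259%. Replicate 1 had 3527 peaks with a q-value under 0.01, so its 3866 highest reach past that cutoff. Replicates 2 and 3 had 4276 and 4599 such peaks.

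The excess of TAATTA at summits over flanks may come from the base composition of the summit windows. Of the 7 other palindromes of the same bases, 7 had a ratio at least as large as that of TAATTA in the optimal list, and 6, 7 and 6 in the lists of replicates 1, 2 and 3. ATTAAT, which itself contains TAAT, is among these 7. For TAATTA sites beyond base composition, the mean log2 ratio to 20 dinucleotide shuffles was -0.067 (bootstrap 95% interval -0.18 to 0.04), against 0.46 over flanks. Summit windows thus held no detectable excess of TAATTA over their own dinucleotide counts. Flank windows were not shuffled, so the usual level of TAATTA relative to shuffles is unknown, and such sites are not excluded as a source of the excess. Other cores also lay below their shuffled windows, such as TAATCC (log2 ratio -0.63), TGACCT (-0.65) and the variant core TAATGA (-0.44), while GAGAGA lay above (1.31). Peaks with TAATTA sites bound by Ems stay possible.

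A candidate explanation for the binding of ribosomal protein genes, beside patterning lists that did not differ detectably from matched genes with the 1 kb window, is that the peaks mark families of ubiquitously used genes in general. The rule written before its result counted against this if 2 or more of the 4 families were not bound more than matched genes. That was met, since proteasome subunit genes (8 of 48, against 9.06 expected) and complex I and cytochrome oxidase genes (14 of 56, against 11.7) did not pass the test. These lists are small and a missed threshold does not show that they equal matched genes, so the explanation is not settled. The share bound ranged from 16.7% to 39.7% over the 4 families. Recovery of any strongly transcribed locus by the immunoprecipitation stays open. Of 290 tRNA genes 7.59% had a summit within 1 kb (exact binomial interval 4.82 to 11.3), below the 22.2% of protein-coding genes, as were the 17.1% of 269 snoRNA genes (12.8 to 22.1) and the 8.68% of 3261 ncRNA genes (7.73 to 9.70), but 28.1% of 32 snRNA genes had one (13.7 to 46.7), and the bound on snRNA genes was added after their share had been seen. No expression data, control tag or second antibody was analysed here, and with 1 group the design names no biological difference to test; binding by Ems itself was not tested.

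The peak in a coding exon of *ems* could come from extra copies of the region on the transgene, which would raise the number of listed peaks there in each replicate. The number of listed peaks within 10 kb of *ems* stood at the 31.1st, 48.5th and 86.3rd percentile of protein-coding genes in replicates 1, 2 and 3, and the number per kb at the 37.5th, 58.0th and 93.4th. Extra copies stay open, since these values spread widely, their bounds were set, and later tightened, after the values had been seen, and the control file used by the authors may hold the same copies. For an open developmental locus with many weak peaks, 47 of 101 genes in the developmental lists (46.5%) had at least as many peaks as *ems* in the joint list, above the bound of 25% set in advance, and 73.3%, 62.4% and 23.8% in replicates 1, 2 and 3. Per kb, a measure not set in advance that allows for gene length and whose values were seen before those of the count, the shares were 12.9% in the joint list and 41.6%, 26.7% and 2.97% in the replicates, so this explanation is not settled, and binding of Ems to its own locus was not tested separately.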
